A study of Mus musculus with 12 samples.

How the data were processed

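Gene expression was measured in mouse pancreatic cells by hybridising biotin-labelled total RNA, extracted with a column kit, to Affymetrix arrays. The series holds 12 arrays, 3 for each of 4 kinds of cells: adult acinar cells, embryonic acinar cells, cultures in acinar-to-ductal metaplasia (ADM) and low-passage tumor cells. The deposited values of all 12 arrays were read as log2 signal per probe set, with 2 decimals, and had been processed by the authors. The base of the logarithm was inferred from their range, 1.56 to 13.67. The labels name neither the software nor the normalization behind the values. The 75th percentile of the values averaged 5.07 on adult, 5.47 on embryonic, 5.48 on ADM and 5.41 on tumor arrays.

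Each array held 41345 probe sets. Of these, 23521 carried 1 gene symbol in the platform annotation, 1814 carried several and 16010 carried none. The first kind gave 22180 distinct genes, and 23328 of its probe sets were matched to a mouse gene by gene identifier with no symbol changed. For the 1082 genes with over 1 probe set, the probe set with the highest mean over all 12 arrays was used. Probe sets with several symbols or none stayed outside the gene tests and were tested separately. Cross-hybridisation between close paralogs, such as amylases, trypsins, kallikreins, stefins and the Reg genes, was not tested. Genes were placed on chromosomes by gene symbol from the mouse reference annotation, and no coordinates are printed.

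All 12 arrays were fitted together, with a mean for each of the 4 groups and no replicate block, using limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes). The fit had 8 residual degrees of freedom per gene, and the prior added 5.02. 5 contrasts were read from it, namely ADM, embryonic and tumor each against adult acinar, tumor against ADM, and ADM against embryonic. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Values after a ± sign beside a fold change are standard errors (SE) from this fit, with n = 3 arrays per group, and those beside a level are standard deviations (SD) over 3 arrays. Each SE uses a spread pooled over all 4 groups, so variable arrays of a group outside the contrast can enlarge it. Tests were two-sided. The number of arrays limits the precision of every value.

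30 gene lists were written from general knowledge of the tissue. They held acinar enzymes, acinar transcription factors, the secretory machinery of the endoplasmic reticulum (ER), ductal markers, pancreatic progenitor factors, oncofetal and imprinted genes, Hox genes, polycomb repressive complexes 1 and 2 (PRC1 and PRC2), the DNA methylation machinery, and histone deacetylases and demethylases. They also held mesenchymal genes, epithelial junction genes, mitosis (G2/M) genes, DNA replication (S phase) genes, EGF receptor and MAPK response genes, Notch genes, YAP and TEAD targets, inflammation and injury genes, gastric and mucin genes, tumour suppressors and oncogenes, glycolysis and oxidative phosphorylation. Markers of cells other than acinar or ductal made up 7 lists: endocrine, fibroblast and stellate, immune, endothelial, neural and Schwann, erythroid, and mesothelial. Together with 15 housekeeping genes kept for scaling, the lists held 621 entries, of which 567 were measured. The 7 lists of other cells shared no member with any other list. Each list except the housekeeping genes was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists of a comparison. The direction of the test and the sign of the median were opposed only in lists that were not called.

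The comparisons, tests, thresholds, lists, alternatives and the choice of named genes were fixed before the data were examined. For each comparison, the named genes were 14 fixed ones (Ptf1a, Nr5a2, Bhlha15, Cpa1, Krt19, Sox9, Pdx1, Rnf2, Bmi1, Ezh2, Cdh1, Vim, Mki67 and Cdkn2a), then the 6 called genes with the largest and the 6 with the smallest log2 fold change, and then up to 4 called members per list by absolute change. The extremes left out predicted genes, receptor gene families and unnamed transcripts, and needed every array of one group to lie above every array of the other.

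A background level was chosen after seeing the data: the 95th percentile of the group means of 1394 olfactory and vomeronasal receptor genes, which lay at 3.62 on the log2 scale. Where the dimmer group of a named gene lay at or under this level, the change is given as a bound, "at least", computed against it. Medians of gene lists were taken after raising every group mean under this level to it.

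Genes called in the same direction in 2 contrasts against adult acinar cells were counted beside the count expected of independent calls. They were also counted in 100 simulations of unchanged groups, in which both contrasts shared the same simulated adult arrays. The alternatives were quantile normalization, cyclic loess and centring on the housekeeping genes, each on top of the deposited values, a filter on dim genes, a fit of only the 6 arrays compared, and the replicate number as a block. Others were an intensity trend with robust hyperparameters, array weights, the mean of all probe sets of a gene, no fold change minimum, an adjusted p under 0.01, each array left out in turn, and, for camera, an inter-gene correlation estimated per list. No scan date or array batch was given in the labels, so a batch could not be tested. The pipeline was tested on simulated data with the design of ADM against adult acinar over 22180 genes. Changes were planted only in genes with a mean signal well above background, so recovery of dim genes was not tested. It called 77.6% of genes changed by 1.5 on the log2 scale, 97.0% of those changed by 2 and 98.5% of those changed by 3, and 3 of 21980 unchanged genes. Figures were drawn with matplotlib 3.10.9.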

Results

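Expression was measured on 12 arrays of mouse pancreatic cells, 3 arrays in each of 4 groups. Adult and embryonic acinar cells, the enzyme-secreting cells of the exocrine pancreas, had been isolated by collagenase digestion and used for RNA directly. ADM cultures were acinar cells kept for 7 days in a collagen gel with 50 ng/ml TGF-alpha, a ligand of the EGF receptor. Low-passage pancreatic tumor cells had grown in standard medium. The labels give the strain as C57Bl6/J wildtype for every sample and number the replicates 1 to 3 in each group. They do not say whether replicates were separate animals or cultures, so the p-values measure only the spread between arrays.

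The arrays separated by group. Correlations across genes within a group lay between 0.967 and 0.991, and those between groups between 0.817 for an adult and a tumor array and 0.938 for an ADM and a tumor array. Genes are not independent, so these values describe likeness only. Adult arrays showed 13521 ± 185 (SD, n = 3) genes above background, embryonic arrays 12958 ± 156, ADM arrays 12479 ± 14.5 and tumor arrays 12113 ± 49.5. The same background level of 3.62 was used for every array. The median probe set lay at 3.66 to 3.72 on adult arrays and at 3.48 to 3.57 on the others. These counts therefore follow the level of dim signal and do not rank the groups by the number of expressed genes. The 25 brightest genes carried 8.25% ± 0.139 (SD, n = 3) of the linear signal on adult arrays and between 6.01% and 6.67% on average in the other groups. The 14 measured housekeeping genes had a median signal of 9.52 on adult, 9.94 on embryonic, 9.85 on ADM and 9.71 on tumor arrays. Over all genes, the median log2 change against adult cells was -0.11 for ADM, -0.09 for embryonic and -0.09 for tumor cells. Centring on the housekeeping genes moved these medians to -0.44, -0.51 and -0.28. It moved the median of tumor against ADM from 0.06 to 0.20. Among genes with a mean over 6 in both groups, the deposited values gave medians against adult cells of the other sign. These were 0.20 for ADM, 0.05 for embryonic and 0.31 for tumor cells, so the negative medians over all genes came from dimmer genes.

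**Figure D1:**
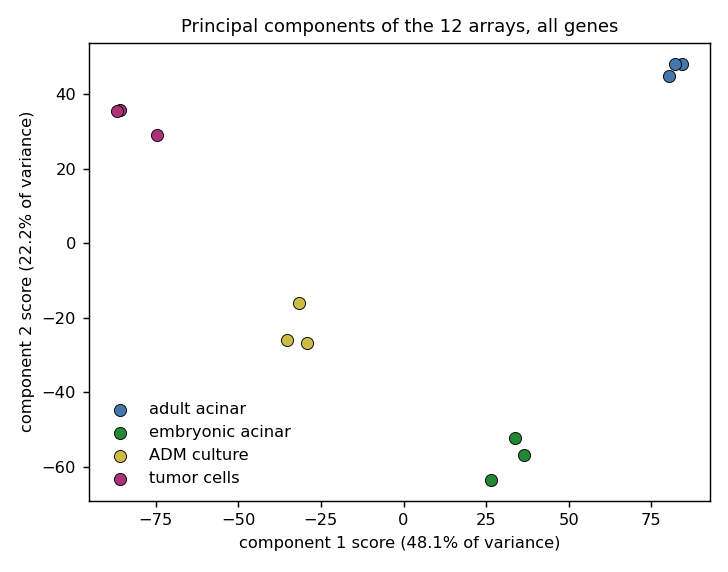
Scores of the 12 arrays on principal component 1 (horizontal, 48.1% of the variance) and component 2 (vertical, 22.2%), computed from the log2 signal of all genes, with 1 point per array colored by group. Adult arrays lay between 80.4 and 84.4 on component 1, embryonic arrays between 26.6 and 36.4, ADM arrays between -35.4 and -29.2, and tumor arrays between -86.8 and -74.8.

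In ADM cultures compared with adult acinar cells, genes of the acinar program were lower, and genes of ducts, proliferation and EGF receptor response were higher. The ductal and EGF receptor lists kept their calls with an estimated correlation, while acinar enzymes (adjusted p = 0.0764), acinar transcription factors (adjusted p = 0.128), mitosis genes (adjusted p = 0.146) and replication genes (adjusted p = 0.116) lost them. Bhlha15, a transcription factor of the secretory acinar cell, fell by 5.89 ± 0.19 (SE, n = 3 per group) on the log2 scale, adjusted p = 3.29e-10. Ptf1a, which drives acinar genes, fell by 2.97 ± 0.36, and the nuclear receptor gene Nr5a2 fell by 1.58 ± 0.23. The duct keratin Krt19 rose by 3.20 ± 0.15, adjusted p = 5.17e-09. The comparison addresses the change from isolated adult acinar cells to a metaplasia culture. Whether other cells in the culture took part in it was not tested. Time, collagen and TGF-alpha entered together, so their parts cannot be separated.

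Of 22180 genes, 2766 were called higher and 935 lower in ADM. Over all genes, called or not, the arrays of the 2 groups did not overlap for 11047, where chance gives 10%. The inducible cyclooxygenase Ptgs2 was at least 204-fold higher, adjusted p = 1.68e-10. Other extremes were the aspartic protease Ctse (7.73 ± 0.39), the cornified envelope gene Sprr1a (7.73 ± 0.22), the protease inhibitor Timp1 (7.13 ± 0.31), the trefoil factor Tff1 (7.07 ± 0.33) and the matrix protease Mmp7 (6.87 ± 0.21). Lowest were Gal, the galanin gene (-7.97 ± 0.25), Tmed11 (-7.85 ± 0.27), the serpin gene Serpini2 (-7.81 ± 0.27) and Ctrc, which encodes chymotrypsin C (-7.07 ± 0.80). The large SE of Ctrc came from embryonic arrays (SD 2.45), since its SD was 0.061 on adult and 0.125 on ADM arrays. Vtn, the vitronectin gene, was at least 153-fold lower and Hamp2, a hepcidin gene, at least 118-fold lower.

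Among 29 measured acinar enzymes 25 fell, with a median of -3.64 (adjusted p = 1.53e-17, and adjusted p = 0.0764 with an estimated correlation). Zg16 fell by 6.63, Amy2b by 6.50 and Pla2g1b by 5.76, whereas Cpa1, carboxypeptidase A1, stood at -0.72 ± 0.18 and was not called. 6 of 9 acinar transcription factors fell, among them Rbpjl by 4.50 ± 0.23 (median -1.58, adjusted p = 0.000387, and adjusted p = 0.128 with an estimated correlation). Of 29 genes of the ER secretory machinery 17 fell, with Ero1b at -5.16 and Sdf2l1 at -3.27 (list adjusted p = 1.44e-13, and adjusted p = 0.0837 with an estimated correlation). 13 of 21 ductal markers rose and 1 fell (median 1.97, adjusted p = 3.55e-08). Cldn4 rose by 6.77, Krt20 by 6.63, Tspan8 by 6.55 and Krt7 by 3.75. Sox9, a factor of ducts and progenitors, stood at -0.56 ± 0.44 (adjusted p = 0.336) and Pdx1 at -0.40 ± 0.19 (adjusted p = 0.116). Epithelial junction genes rose in 9 of 23 cases and fell in 1 (adjusted p = 0.000122, and adjusted p = 0.147 with an estimated correlation), and the cadherin Cdh1 rose by 1.52 ± 0.18.

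Mesenchymal genes rose in 16 of 18 cases (median 2.89, adjusted p = 3.49e-12, and adjusted p = 0.0658 with an estimated correlation). Fn1, which encodes fibronectin, rose by 6.17, the collagen crosslinker Lox by 5.94, Tnc by 5.72 and Vim by 2.09 ± 0.19. Markers of fibroblasts and stellate cells moved with them, and whether both came from acinar or from other cells was not tested. 14 of 20 rose, among them Postn by 6.20 and Col1a2 by 3.88 (list adjusted p = 1.33e-07, and adjusted p = 0.188 with an estimated correlation). All 24 mitosis genes rose (median 2.47, adjusted p = 7.16e-15, and adjusted p = 0.146 with an estimated correlation), with Cdk1 at 4.29 ± 0.36 and Mki67 at 1.98 ± 0.31. In the DNA replication list 21 of 24 rose, led by the helicase gene Mcm6 at 4.01 ± 0.15 (list adjusted p = 1.77e-12, and adjusted p = 0.116 with an estimated correlation). 17 of 20 EGF receptor and MAPK response genes rose (median 2.32, adjusted p = 1.07e-13), including the ligands Ereg by 5.14 and Hbegf by 3.61. YAP and TEAD targets rose in 15 of 17 cases (median 2.26, adjusted p = 6.21e-11), with Ccn2 at 5.59 and Ankrd1 at least 48.5-fold higher.

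The histone methyltransferase gene Ezh2 rose by 2.64 ± 0.23, and 6 of 12 PRC2 genes rose (median 0.82, adjusted p = 0.000274). For PRC1, 6 of 19 rose, with Pcgf5 at 1.27 and Pcgf3 at 1.25 (list adjusted p = 0.00744, and adjusted p = 0.0658 with an estimated correlation). Rnf2, the ubiquitin ligase of PRC1, was called at 1.25 ± 0.17, and Bmi1 stood at 0.34 ± 0.26. Under quantile normalization, cyclic loess and housekeeping centring, Rnf2 lay at 0.81, 0.90 and 0.93 and was no longer called, as for Pcgf5 and Pcgf3. The PRC1 list call was lost under quantile normalization (adjusted p = 0.436), loess (adjusted p = 0.433) and with dim genes left out (adjusted p = 0.124). It was kept under housekeeping centring (adjusted p = 0.0134), where the median of the list was -0.0017. 2 of 10 DNA methylation genes rose, Dnmt1 by 2.40 and Uhrf1 by 2.32 (list adjusted p = 0.0329, and adjusted p = 0.128 with an estimated correlation). 9 of 25 histone deacetylases and demethylases rose and 2 fell, with Hdac1 at 3.21 and Kdm1a at 1.95 (list adjusted p = 0.00176, and adjusted p = 0.128 with an estimated correlation). Both list calls were lost under quantile normalization, under cyclic loess (adjusted p = 0.148 for DNA methylation and adjusted p = 0.103 for the histone enzymes) and with dim genes left out (adjusted p = 0.153 and adjusted p = 0.0614). DNA methylation also lost its call under housekeeping centring (adjusted p = 0.0609).

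Gastric and mucin genes rose in 9 of 19 cases and fell in 2, with Gcnt3 at 5.99 and Muc5ac at least 48.1-fold higher (list adjusted p = 0.00401, and adjusted p = 0.147 with an estimated correlation), a list call also lost with dim genes left out (adjusted p = 0.0613). 9 of 21 inflammation and injury genes rose, among them Lcn2 by 5.13 ± 0.76 (list adjusted p = 0.00058, and adjusted p = 0.087 with an estimated correlation). The SE of Lcn2 came mainly from tumor arrays (SD 2.31), since its SD was 0.062 on adult and 0.22 on ADM arrays. In the list of tumour suppressors and oncogenes 3 of 8 rose, Cdkn1a by 2.44, Mdm2 by 2.21 and Cdkn2b by 1.94 (list adjusted p = 0.0001), while Cdkn2a stood at 0.71 ± 0.17 (adjusted p = 0.00601). Glycolysis genes rose in 11 of 14 cases, with Slc2a1 at 2.83 and Pkm at 2.37 (list adjusted p = 1.08e-07, and adjusted p = 0.128 with an estimated correlation). Oxidative phosphorylation genes shifted down with a median of -0.39, with 1 of 29 called (adjusted p = 3.77e-05, and adjusted p = 0.188 with an estimated correlation). The other 10 lists did not pass, with adjusted p from 0.162 for endocrine markers to 0.748 for immune markers. These included Hox genes, of which 1 of 36 was called, Notch genes (2 higher and 3 lower of 17) and the oncofetal list (4 higher and 2 lower of 16). The mesothelial marker Msln rose by 6.33 although its list did not.

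In all, 20 of 30 lists were called, 16 higher and 4 lower, and 5 of these calls held with an estimated correlation: ductal markers, PRC2, EGF receptor response, YAP targets and tumour suppressors. Counts adjusted over the list alone were the same, except for 1 fibroblast marker more (lower) and 1 erythroid marker fewer (higher). The share of calls that were higher, 74.7%, fell to 59.4% with quantile normalization, 59.4% with cyclic loess and 46.4% with housekeeping centring.

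**Figure D2:**
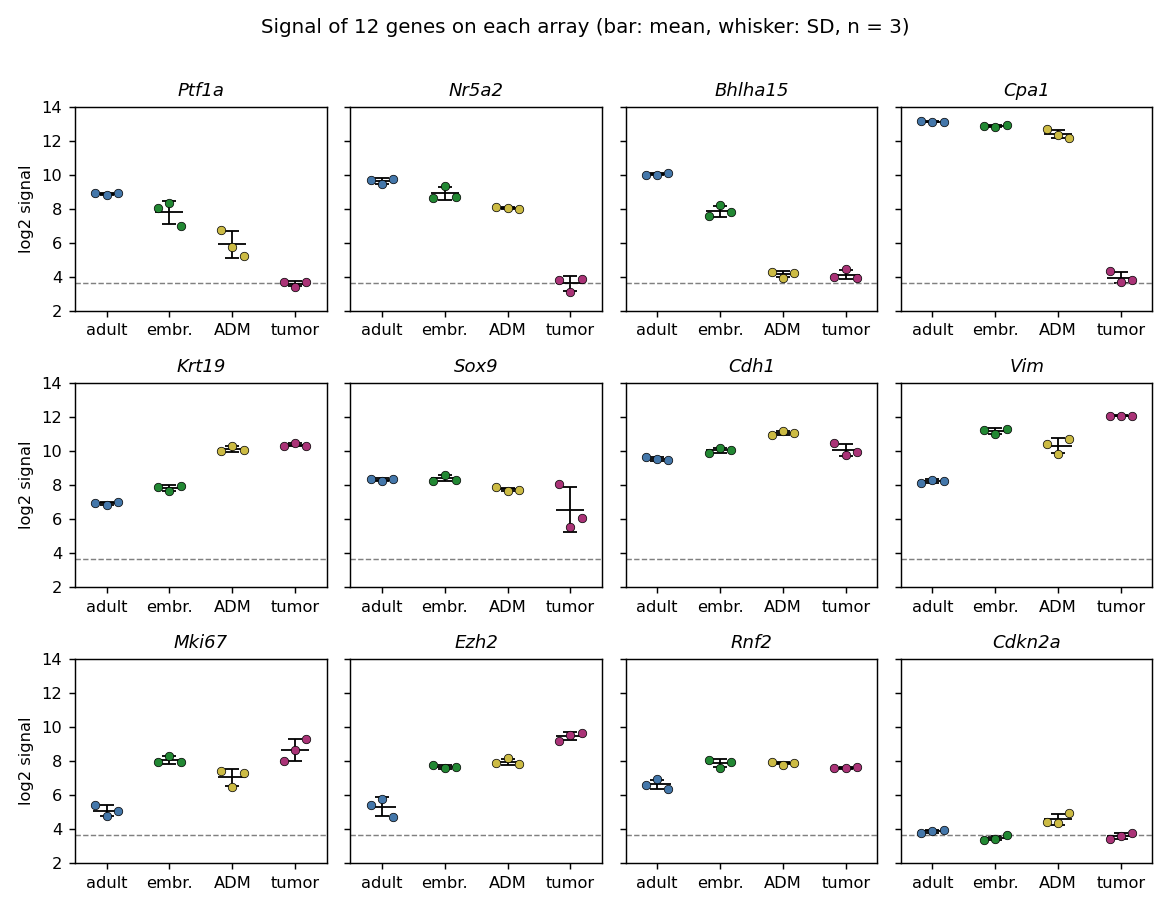
Log2 signal (vertical) of 12 fixed genes on each array by group, with 1 point per array, a bar for the mean and a whisker for the SD of 3 arrays; the dashed line marks the background level of 3.62. Cpa1 averaged 13.13 on adult, 12.89 on embryonic, 12.41 on ADM and 3.96 on tumor arrays.

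Embryonic acinar cells compared with adult acinar cells had higher signal of proliferation genes and of oncofetal genes, and several enzyme genes at lower levels. Oncofetal genes kept their call with an estimated correlation, while mitosis genes (adjusted p = 0.0905), replication genes (adjusted p = 0.0592) and acinar enzymes (adjusted p = 0.261) lost theirs. The imprinted gene Mest rose by 5.72 ± 0.34 (SE, n = 3 per group), adjusted p = 1.14e-07, and the growth factor Igf2 rose by 4.94 ± 0.19, adjusted p = 5.08e-09. Bhlha15 fell by 2.18 ± 0.19, whereas Cpa1 stood at -0.24 ± 0.18 (adjusted p = 0.336). Lists of 7 other cell types were also called higher in the embryonic samples, beside each of these groups, and 2 of them lost the call with an estimated correlation, fibroblast (adjusted p = 0.0599) and erythroid markers (adjusted p = 0.13). The comparison sets isolates labelled embryonic acinar cells against isolates labelled adult acinar cells. Development and any difference in their mix of cells cannot be separated.

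Of 22180 genes, 2217 were called higher and 580 lower, and the arrays of the groups did not overlap for 9510 of all genes (chance gives 10%). The calprotectin gene S100a8 was at least 82.5-fold higher (adjusted p = 5.08e-09), the stefin Stfa3 at least 49.4-fold and the fatty acid carrier Fabp1 at least 95.0-fold. The related genes Stfa1 and Fabp2 rose by 6.97 ± 0.29 and 6.94 ± 0.55, and the linker histone gene H1f5 by 6.95 ± 0.43. Lowest were the lectins Reg3a (-6.24 ± 1.04) and Reg2 (-5.88 ± 1.40), Ctrc (-4.73 ± 0.80), Itih4 (-4.61 ± 0.57), Hamp2 (-4.61 ± 0.73) and the hormone gene Fgf21 (-4.19 ± 0.53).

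All 24 mitosis genes rose (median 3.00, adjusted p = 1.09e-20, and adjusted p = 0.0905 with an estimated correlation), with Cdk1 at 4.83 and Mki67 at 2.99 ± 0.31. Of 24 replication genes 23 rose, Mcm6 by 4.10 (list adjusted p = 7.51e-17, and adjusted p = 0.0592 with an estimated correlation). Oncofetal and imprinted genes rose in 13 of 16 cases (median 2.94, adjusted p = 1.11e-13), with Gpc3 at 4.55 and Peg3 at 4.42. 7 of 20 progenitor factors rose and 1 fell (adjusted p = 0.00261, and adjusted p = 0.123 with an estimated correlation). Neurog3, the endocrine progenitor factor, was at least 28.5-fold higher, Pdx1 stood at 0.58 ± 0.19 (adjusted p = 0.037) and Sox9 at 0.09 ± 0.44. 9 of 29 acinar enzymes fell, with Pla2g1b at -3.27 and Cela3a at -3.21 (median -0.59, adjusted p = 4.39e-05, and adjusted p = 0.261 with an estimated correlation). 3 of 9 acinar transcription factors fell (adjusted p = 0.0187, and adjusted p = 0.261 with an estimated correlation). The list call also ended under housekeeping centring (adjusted p = 0.0752), without embryonic replicate 3 (adjusted p = 0.0596) and without adult replicate 1 (adjusted p = 0.0503). Ptf1a was called at -1.08 ± 0.36 (adjusted p = 0.0393), and its adjusted p lay from 0.0243 to 0.156 as each of the 6 arrays was left out, with the call lost in 5 cases. The Ptf1a call was also lost with array weights and with the mean of its probe sets. Nr5a2 stood at -0.73 ± 0.23. ER secretory genes fell in 5 of 29 cases (adjusted p = 0.000133, and adjusted p = 0.261 with an estimated correlation).

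Mesenchymal genes rose in 14 of 18 cases (median 2.50, adjusted p = 4.99e-12), Fn1 by 4.63, Mmp14 by 4.10 and Vim by 2.96 ± 0.19. 9 of 21 ductal markers rose (adjusted p = 2.09e-06), among them Tspan8 by 3.33 and Ambp by 2.71, while Krt19 stood at 0.90 ± 0.15 under the fold minimum. Among EGF receptor and MAPK response genes 10 of 20 rose (adjusted p = 0.000328, and adjusted p = 0.0923 with an estimated correlation), and among YAP and TEAD targets 8 of 17 rose and 1 fell (adjusted p = 0.000119, and adjusted p = 0.0904 with an estimated correlation). Notch genes rose in 5 of 17 cases and fell in 2, with Hey1 at 1.94 and Dtx1 at -2.39 (list adjusted p = 0.0103, and adjusted p = 0.0923 with an estimated correlation). That call was lost under quantile normalization (adjusted p = 0.0631) and with dim genes left out (adjusted p = 0.143). Glycolysis genes rose in 5 of 14 cases (adjusted p = 0.00105, and adjusted p = 0.262 with an estimated correlation).

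Ezh2 rose by 2.35 ± 0.23 and 4 of 12 PRC2 genes rose (adjusted p = 0.00646, and adjusted p = 0.0592 with an estimated correlation), a list call lost under quantile normalization (adjusted p = 0.0779), cyclic loess (adjusted p = 0.0504) and with dim genes left out (adjusted p = 0.0799). Rnf2 was called at 1.25 ± 0.17, but lay at 0.92 under quantile normalization and 0.83 under housekeeping centring. The PRC1 list did not pass (adjusted p = 0.106), and Bmi1 stood at 0.07 ± 0.26. 4 of 10 DNA methylation genes rose, with Uhrf1 at 2.94 and Dnmt1 at 2.62 (list adjusted p = 0.00101). Of 25 histone deacetylases and demethylases 4 rose and 1 fell, with Hdac1 at 2.92 (list adjusted p = 0.00782, and adjusted p = 0.159 with an estimated correlation), a call lost under quantile normalization (adjusted p = 0.257), cyclic loess (adjusted p = 0.197) and with dim genes left out (adjusted p = 0.143). Cdh1 stood at 0.51 ± 0.18, and Cdkn2a lay at 3.46 on embryonic arrays, under the background level.

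All 20 fibroblast and stellate markers rose (median 2.89, adjusted p = 1.94e-18, and adjusted p = 0.0599 with an estimated correlation), with Postn at 6.52 and Col1a2 at 4.81. 15 of 17 endocrine markers rose (median 2.81, adjusted p = 2.56e-13), Pyy by 4.52 and Chgb by 4.28. Immune markers rose in 12 of 18 cases, led by Tyrobp at 4.15 (list adjusted p = 1.14e-07), and endothelial markers in 12 of 14, with Cdh5 at 2.54 (list adjusted p = 5.53e-12). 6 of 6 mesothelial markers rose, Upk3b by 3.62 (list adjusted p = 3.23e-06), and 5 of 9 neural and Schwann markers, Stmn2 by 3.48 (list adjusted p = 0.00189). Erythroid markers rose in 2 of 9 cases (median 0.20, adjusted p = 0.0419, and adjusted p = 0.13 with an estimated correlation), a call also lost with dim genes left out (adjusted p = 0.243) and with only the 6 arrays compared (adjusted p = 0.0684). It was lost too without embryonic replicate 2 (adjusted p = 0.0951) and without adult replicates 1 (adjusted p = 0.0508) or 2 (adjusted p = 0.0575).

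In this comparison 23 of 30 lists were called, 20 higher and 3 lower. The 9 calls that held with an estimated correlation were ductal, oncofetal, DNA methylation, mesenchymal, endocrine, immune, endothelial, neural and mesothelial genes. Lists of Hox, epithelial junction, inflammation, gastric, tumour suppressor and oxidative phosphorylation genes did not pass, with adjusted p from 0.502 to 0.895. Adjusted over the list alone, 1 acinar enzyme more and 1 ductal marker fell and 1 gastric gene more rose. The share of calls that were higher was 79.3%, against 64.0% with quantile normalization, 69.1% with cyclic loess and 35.8% with housekeeping centring.

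**Figure D3:**
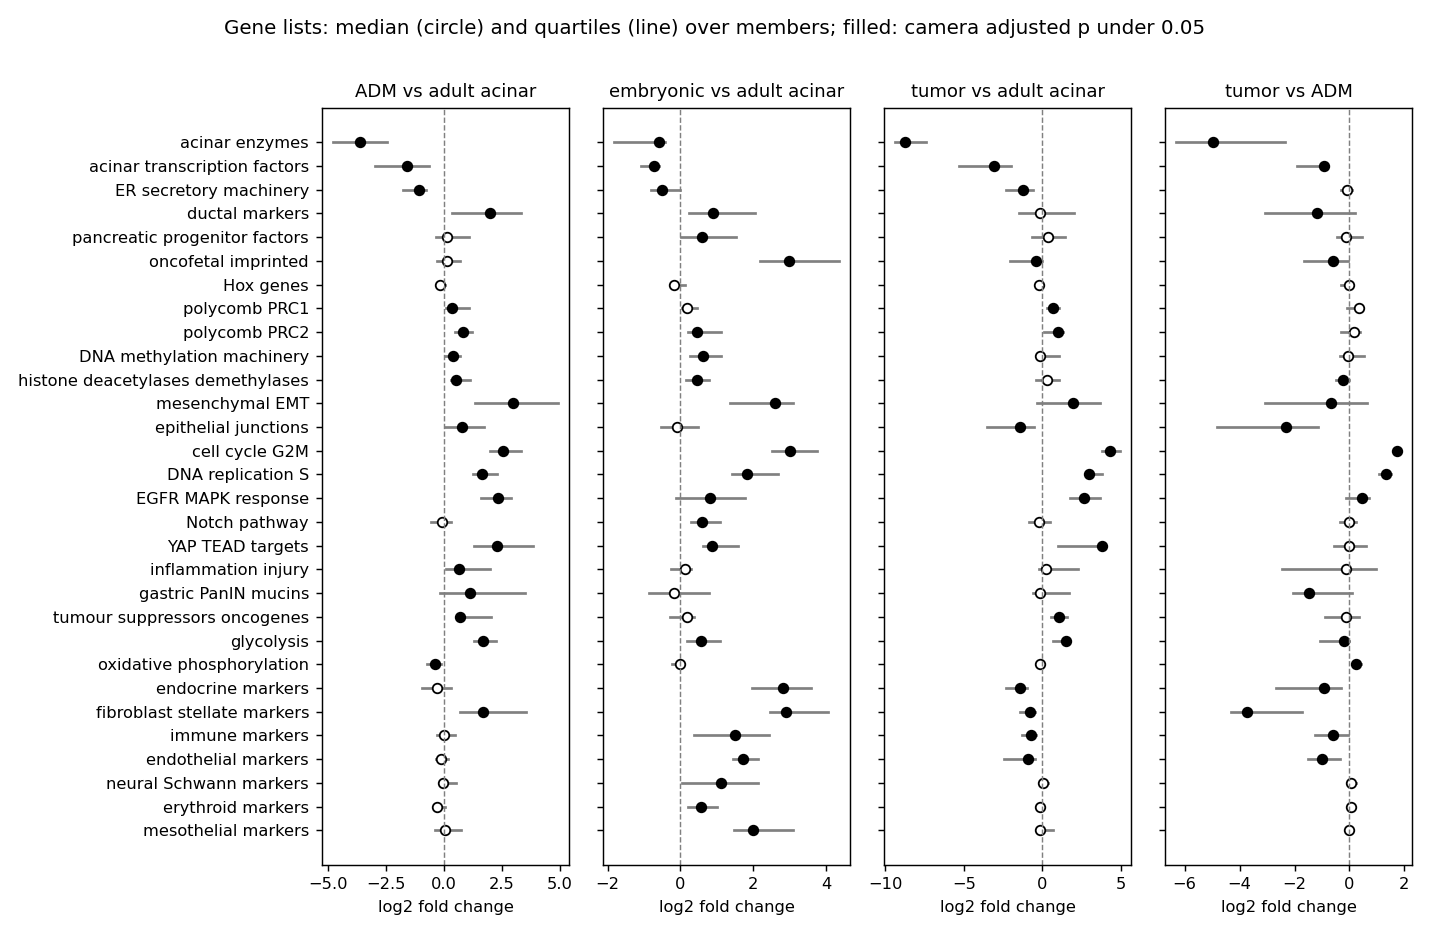
Median (circle) and quartiles (line) of the log2 fold change (horizontal) over the measured members of 30 gene lists (vertical) in 4 comparisons, each with its own horizontal scale; filled circles have a camera adjusted p under 0.05. These medians use the fitted values with no background level applied, so that acinar enzymes lie at -3.64, -0.59, -8.77 and -4.97 from left to right.

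Tumor cells compared with adult acinar cells had lower signal of most acinar genes and of many epithelial junction genes, and higher signal of proliferation genes. Acinar enzymes kept their call with an estimated correlation, while acinar transcription factors (adjusted p = 0.0572), junction genes (adjusted p = 0.0572), mitosis genes (adjusted p = 0.0992) and replication genes (adjusted p = 0.0572) lost theirs. Ptf1a was at least 38.3-fold lower (adjusted p = 9.88e-08) and Nr5a2 at least 65.3-fold lower (adjusted p = 4.68e-10), both at background on tumor arrays. Cpa1 fell by 9.17 ± 0.18 (SE, n = 3 per group), and Bhlha15 by 5.92 ± 0.19. Krt19 rose by 3.45 ± 0.15 and Ezh2 by 4.14 ± 0.23. The comparison addresses how far a cultured tumor cell stands from the normal acinar cell, with growth in culture and tumor origin confounded.

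Of 22180 genes, 3108 were called higher and 1321 lower, and the arrays did not overlap for 9687 of all genes (chance gives 10%). The YAP target Ankrd1 was at least 144-fold higher and the chemokine Cxcl5 at least 130-fold higher. Anxa3 (7.10 ± 0.35), Sprr1a (7.10 ± 0.22), Plac8 (6.98 ± 0.33) and the integrin Itga2 (6.79 ± 0.26) followed. Secreted acinar products were lowest. Sycn was at least 719-fold lower, Pnliprp2 at least 624-fold, Klk1 at least 617-fold, Rnase1 at least 458-fold, Cpb1 at least 451-fold and Spink1 at least 446-fold.

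28 of 29 acinar enzymes fell (median -8.62, adjusted p = 1.06e-31), as did 7 of 9 acinar transcription factors, Rbpjl by 5.30 (list adjusted p = 1.75e-07, and adjusted p = 0.0572 with an estimated correlation). ER secretory genes fell in 19 of 29 cases, with Ero1b at -6.13 and Sel1l at -4.01 (list adjusted p = 1.19e-13, and adjusted p = 0.0687 with an estimated correlation). Among 23 epithelial junction genes 14 fell and 0 rose (median -1.42, adjusted p = 3.06e-09, and adjusted p = 0.0572 with an estimated correlation). Prss8 fell by 6.09 and Spint1 by 5.23, Rab25 was at least 38.3-fold lower, and the splicing regulator Esrp1 at least 16.3-fold lower. Cdh1 stood at 0.53 ± 0.18 and was not called. Ductal markers went both ways, 9 higher and 7 lower of 21 (adjusted p = 0.598), with Tspan8 at 6.76, Krt7 at 4.31 and Cldn7 lower by at least 3.58 on the log2 scale. The median of that list was -0.11 while its test pointed up. Sox9 fell by 1.75 ± 0.44 (adjusted p = 0.00671), with a tumor level of 6.55 ± 1.32 (SD, n = 3), and Pdx1 rose by 1.58 ± 0.19 (adjusted p = 1.77e-05).

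All 24 mitosis genes (median 4.30, adjusted p = 2.5e-20, and adjusted p = 0.0992 with an estimated correlation) and all 24 replication genes (median 2.99, adjusted p = 2.94e-18, and adjusted p = 0.0572 with an estimated correlation) rose. Cdk1 stood at 6.09, the survivin gene Birc5 at 5.52, Mki67 at 3.56 ± 0.31 and Mcm6 at 4.57. Of 20 EGF receptor and MAPK response genes 18 rose (median 2.63, adjusted p = 9.01e-14), among them Hbegf by 4.84, Epha2 by 4.61 and the cyclin gene Ccnd1 by 4.19. YAP and TEAD targets rose in 11 of 17 cases (median 3.73, adjusted p = 4.48e-09), Myof by 5.27 and F3 by 4.87. Mesenchymal genes rose in 10 of 18 cases and fell in 2 (adjusted p = 0.00374, and adjusted p = 0.349 with an estimated correlation), with Fn1 at 5.85, S100a4 at 5.63 and Vim at 3.86 ± 0.19. Glycolysis genes rose in 10 of 14 cases and fell in 1, with Hk2 at 3.17 (list adjusted p = 2.42e-05, and adjusted p = 0.219 with an estimated correlation).

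6 of 12 PRC2 genes rose (median 1.01, adjusted p = 0.00378, and adjusted p = 0.0572 with an estimated correlation). 5 of 19 PRC1 genes rose, Pcgf5 by 1.86 and Pcgf6 by 1.50 (median 0.68, adjusted p = 0.00104). The PRC1 list call was lost under quantile normalization (adjusted p = 0.109) and cyclic loess (adjusted p = 0.0991). Rnf2 stood at 0.99 ± 0.17 and Bmi1 at 0.84 ± 0.26, neither called. Uhrf1 rose by 4.17 and Dnmt1 by 3.37, although the DNA methylation list did not pass (3 of 10 higher, adjusted p = 0.26), nor did the histone deacetylases and demethylases (7 higher and 3 lower of 25, adjusted p = 0.105). 4 of 8 tumour suppressors and oncogenes rose (adjusted p = 0.00821, and adjusted p = 0.0572 with an estimated correlation), a list call also lost with dim genes left out (adjusted p = 0.0542). Cdkn2a lay at 3.60 on tumor arrays, under the background level. 1 oncofetal gene rose, Hmga2 by 3.94, and 5 of 16 fell, among them Grb10 by 3.38 (list adjusted p = 0.00958, and adjusted p = 0.194 with an estimated correlation).

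Lists of 4 of the 7 other cell types were called lower, and neural (adjusted p = 0.737), erythroid (adjusted p = 0.761) and mesothelial markers (adjusted p = 0.859) did not pass. Endocrine markers fell in 12 of 17 cases, Gcg by 4.35 (list adjusted p = 5.24e-08, and adjusted p = 0.0786 with an estimated correlation). 7 of 14 endothelial markers fell and 1 rose, with Cdh5 at -3.66 (list adjusted p = 1.28e-05). 8 of 20 fibroblast and stellate markers fell, with Dcn at least 53.5-fold lower (list adjusted p = 0.000221, and adjusted p = 0.369 with an estimated correlation). Immune markers fell in 5 of 18 cases and rose in 1 (adjusted p = 0.00638, and adjusted p = 0.249 with an estimated correlation). In all, 9 lists were called higher and 9 lower, and 5 calls held with an estimated correlation: acinar enzymes, PRC1, EGF receptor response, YAP targets and endothelial markers. The other 12 lists did not pass, with adjusted p from 0.0673 for Hox genes, of which 0 of 36 were called, to 0.897 for gastric genes. Adjusted over the list alone, 1 YAP target more rose and 1 endocrine marker more fell. The share of calls that were higher was 70.2%, against 57.4% with quantile normalization, 53.0% with cyclic loess and 58.2% with housekeeping centring.

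Tumor cells compared with ADM cultures had lower acinar enzymes and epithelial junction genes, and higher proliferation genes. The calls of mitosis genes (adjusted p = 0.154) and replication genes (adjusted p = 0.0805) were lost with an estimated correlation, and the other 2 were kept. Cpa1 fell by 8.45 ± 0.18 (SE, n = 3 per group), adjusted p = 2e-11, Ptf1a was at least 4.90-fold lower and Nr5a2 at least 21.8-fold lower. Ezh2 rose by 1.50 ± 0.23 (adjusted p = 0.00063), Mki67 by 1.58 ± 0.31, Vim by 1.77 ± 0.19 and Pdx1 by 1.99 ± 0.19. Bhlha15 differed by -0.03 ± 0.19 (adjusted p = 0.964) and Krt19 by 0.25 ± 0.15 (adjusted p = 0.341). The comparison sets low-passage tumor cells against ADM cultures. Tumor origin, growth conditions, passage and any difference in the mix of cells were confounded, so their parts cannot be separated.

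Of 22180 genes, 727 were called higher and 1125 lower, and the arrays did not overlap for 7006 of all genes (chance gives 10%). Lowest were Reg1 (at least 467-fold), Reg3b (-8.64 ± 0.87), the chymotrypsinogen gene Ctrb1 (-8.60 ± 0.27), the proteoglycan gene Bgn (-8.11 ± 0.23) and Reg2 (at least 176-fold). The adhesion gene Tns4 rose by 5.19 ± 0.25. The receptor genes Tigit and Il5ra were at least 32.1-fold and 26.2-fold higher, the phosphatase gene Ptpn22 at least 26.4-fold and Spink4 at least 19.9-fold. Clca3b was called at least 16.9-fold higher (adjusted p = 0.0256). Its adjusted p lay from 1.21e-07 to 0.127 as each of the 6 arrays was left out, and the call was lost in 5 cases, as well as in the fit of only the 6 arrays and with an intensity trend.

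26 of 29 acinar enzymes fell (median -4.97, adjusted p = 2.11e-38), Prss2 by at least 166-fold. 18 of 23 epithelial junction genes fell and 0 rose (median -2.32, adjusted p = 1.3e-35). Cldn4 was at least 118-fold lower, Rab25 at least 51.4-fold and Cldn7 at least 46.9-fold, Spint1 fell by 5.52 and Epcam by 5.27, and Cdh1 stood at -0.99 ± 0.18, not called. 10 of 21 ductal markers fell and 1 rose (median -1.19, adjusted p = 2.69e-07), and Sox9 stood at -1.19 ± 0.44 (adjusted p = 0.0972). Acinar transcription factors fell in 4 of 9 cases (adjusted p = 2.69e-07, and adjusted p = 0.0553 with an estimated correlation). Gastric and mucin genes fell in 11 of 19 cases and rose in 1, with Muc5ac at least 48.1-fold lower and Muc1 at -2.54 (list adjusted p = 1.63e-06, and adjusted p = 0.0542 with an estimated correlation).

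Markers of fibroblasts and stellate cells fell in 17 of 20 cases (median -3.54, adjusted p = 1.96e-27, and adjusted p = 0.0542 with an estimated correlation), with Col1a2 at least 98.3-fold and Postn at least 82.3-fold lower. 7 of 18 mesenchymal genes fell and 2 rose (adjusted p = 0.000278, and adjusted p = 0.305 with an estimated correlation), with Lox at -6.32, Tnc at -5.93 and Sparc at -4.70. 7 of 14 endothelial markers fell and 1 rose, with Eng at -4.49 (list adjusted p = 3.26e-09). Endocrine markers fell in 8 of 17 cases, Iapp by 3.81 (list adjusted p = 1.06e-09, and adjusted p = 0.0647 with an estimated correlation). Immune markers fell in 5 of 18 cases and rose in 1, with the lysozyme gene Lyz2 at least 50.7-fold lower (list adjusted p = 8.22e-05, and adjusted p = 0.135 with an estimated correlation).

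All 24 mitosis genes rose (median 1.74, adjusted p = 2.18e-17, and adjusted p = 0.154 with an estimated correlation), with Cdc20 at 2.22 and Foxm1 at 2.07, and 19 of 24 replication genes rose, Tk1 by 2.32 (list adjusted p = 1.55e-15, and adjusted p = 0.0805 with an estimated correlation). Oxidative phosphorylation genes shifted up by a median of 0.23 with none of 29 called (adjusted p = 0.000615, and adjusted p = 0.351 with an estimated correlation). 6 of 16 oncofetal and imprinted genes fell and 1 rose, with Peg3 at least 62.2-fold lower and Grb10 at -3.60 (list adjusted p = 7.01e-06, and adjusted p = 0.0542 with an estimated correlation). Neither polycomb list passed (PRC1 adjusted p = 0.268, PRC2 adjusted p = 0.974), with Rnf2 at -0.27 ± 0.17 and Bmi1 at 0.51 ± 0.26. Cdkn2b fell by 2.49 ± 0.19 (adjusted p = 1.06e-06), and Cdkn2a, at background on tumor arrays, was not called.

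Lists called higher numbered 4 and lists called lower 13, and the 4 calls that held with an estimated correlation were acinar enzymes, ductal markers, epithelial junction genes and endothelial markers. The remaining 3 called lists passed narrowly: EGF receptor response (higher, adjusted p = 0.0476), glycolysis and histone deacetylases and demethylases (lower, both adjusted p = 0.0387). With an estimated correlation they had adjusted p = 0.351, adjusted p = 0.552 and adjusted p = 0.351. Other alternatives also ended these calls: 5 for the EGF receptor list (adjusted p from 0.063 to 0.556, the highest without tumor replicate 1), 4 for glycolysis (adjusted p from 0.126 to 0.233) and 6 for the histone list (adjusted p from 0.0545 to 0.126). Adjusted over the list alone, 1 more ductal marker, inflammation gene, gastric gene, glycolysis gene and fibroblast marker fell, and 1 more YAP target and gastric gene rose. The 13 lists that did not pass, Notch genes and YAP targets among them, had adjusted p from 0.0954 to 0.974. Of the calls 39.3% were higher, against 51.4% with housekeeping centring.

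ADM cultures compared with embryonic acinar cells, the 2 states that both differ from the mature acinar cell, had less signal of acinar and fetal genes and more of ductal, gastric and injury genes. With an estimated correlation acinar transcription factors (adjusted p = 0.109) and gastric genes (adjusted p = 0.056) lost their calls, and acinar enzymes, oncofetal, ductal and injury genes kept theirs. Bhlha15 fell by 3.71 ± 0.19 (SE, n = 3 per group), adjusted p = 2.05e-08, and Ptf1a by 1.89 ± 0.36 (adjusted p = 0.00223). Krt19 rose by 2.30 ± 0.15 (adjusted p = 1.39e-07). Rnf2 differed by 0.00 ± 0.17, Ezh2 by 0.29 ± 0.23 and Bmi1 by 0.27 ± 0.26, and none was called. Lists of all 7 other cell types were called lower in ADM, beside each of these groups. With an estimated correlation 3 of them lost the call: fibroblast (adjusted p = 0.216), neural (adjusted p = 0.0797) and mesothelial markers (adjusted p = 0.0623).

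Of 22180 genes, 1010 were called higher and 1088 lower, and the arrays did not overlap for 8330 of all genes (chance gives 10%). Tff1 was at least 218-fold higher, Ptgs2 at least 204-fold, the keratinocyte gene Ivl at least 110-fold and Muc5ac at least 48.1-fold, and Mmp7 rose by 6.91 ± 0.21 and Ctse by 6.80 ± 0.39. Fabp1 was at least 95.0-fold lower, S100a9 at least 79.3-fold and Stfa3 at least 49.4-fold, while Serpini2 (-6.99 ± 0.27), Stfa1 (-6.94 ± 0.29) and Tmed11 (-6.75 ± 0.27) fell.

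21 of 29 acinar enzymes fell (median -2.33, adjusted p = 9.02e-19), Zg16 by 5.88 and Amy2b by 5.31, with Cpa1 at -0.48 ± 0.18 (adjusted p = 0.101). 4 of 9 acinar transcription factors fell (adjusted p = 0.000456, and adjusted p = 0.109 with an estimated correlation), with Nr5a2 at -0.85 ± 0.23 and not called. ER secretory genes fell in 7 of 29 cases (adjusted p = 2.4e-14). 11 of 16 oncofetal and imprinted genes fell and 1 rose (median -2.62, adjusted p = 1.06e-14), with Gpc3 at -5.73 and Igf2 at -5.12. Notch genes fell in 6 of 17 cases, Hey1 by 1.85 (list adjusted p = 0.000117). 11 of 21 ductal markers rose and 3 fell, with Cldn4 at 4.37 and Krt20 at 3.98 (list adjusted p = 9.42e-06), and 10 of 23 epithelial junction genes rose, Elf3 by 2.81 (list adjusted p = 5.91e-10). Gastric and mucin genes rose in 10 of 19 cases and fell in 4 (median 0.92, adjusted p = 6.01e-05, and adjusted p = 0.056 with an estimated correlation). 11 of 21 inflammation and injury genes rose, Lcn2 by 3.89 (list adjusted p = 8.92e-08). 12 of 20 EGF receptor and MAPK response genes rose, Ereg by 5.26 (list adjusted p = 1.51e-10), as did 8 of 17 YAP and TEAD targets, Ccn2 by 4.02 (list adjusted p = 1.2e-10).

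5 of 8 tumour suppressors and oncogenes rose (median 1.02, adjusted p = 5.22e-06), Cdkn2b by 2.18. Cdkn2a lay at background on embryonic arrays and was at least 1.92-fold higher, a bound under the fold minimum, so its call rested on signal under background. Glycolysis genes rose in 8 of 14 cases, Pkm by 1.85 (list adjusted p = 2.68e-07, and adjusted p = 0.109 with an estimated correlation), and oxidative phosphorylation genes shifted by a median of -0.39 with none of 29 called (adjusted p = 4.31e-07, and adjusted p = 0.115 with an estimated correlation). 6 of 18 mesenchymal genes rose and 2 fell (adjusted p = 0.0123, and adjusted p = 0.32 with an estimated correlation), and Vim stood at -0.87 ± 0.19. Mitosis genes shifted by a median of -0.53 with 2 of 24 called lower (adjusted p = 0.00151, and adjusted p = 0.451 with an estimated correlation). Mki67 was called at -1.01 ± 0.31 (adjusted p = 0.0405), with an adjusted p from 0.0407 to 0.187 as each array was left out and the call lost in 5 of 6 cases, and also under housekeeping centring, with array weights and with the replicate block. Cdh1, called at 1.01 ± 0.18, lay between 0.93 and 1.08 in those fits and lost its call in 3 of 6, and also under cyclic loess and with array weights. Sox9 stood at -0.66 ± 0.44 and Pdx1 at -0.98 ± 0.19, neither called.

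15 of 17 endocrine markers fell (median -3.22, adjusted p = 2.13e-21), Sst by 5.67, and 13 of 14 endothelial markers fell, Pecam1 by 2.89 (list adjusted p = 1.88e-16). Immune markers fell in 12 of 18 cases (adjusted p = 1.15e-11) and erythroid markers in 2 of 9 (adjusted p = 0.00167). Fibroblast and stellate markers fell in 12 of 20 cases and rose in 2 (adjusted p = 2.35e-06, and adjusted p = 0.216 with an estimated correlation). 5 of 6 mesothelial markers fell and Msln rose (list adjusted p = 0.000525, and adjusted p = 0.0623 with an estimated correlation), and 3 of 9 neural and Schwann markers fell (adjusted p = 0.0294, and adjusted p = 0.0797 with an estimated correlation). In all, 25 of 30 lists were called, 9 higher and 16 lower, and 14 held with an estimated correlation. The 14 included acinar enzymes, ER secretory, ductal, epithelial junction, endocrine and endothelial genes. Progenitor factors (adjusted p = 0.0484) and replication genes (adjusted p = 0.0362) were called lower and had adjusted p = 0.254 and adjusted p = 0.491 with an estimated correlation. Other alternatives also ended these calls, 6 for progenitor factors (adjusted p from 0.0543 to 0.0786) and 4 for replication genes (adjusted p from 0.0602 to 0.133, the highest without ADM replicate 2). The neural list lost its call without embryonic replicate 2 (adjusted p = 0.0629). Hox, PRC1, PRC2, DNA methylation and histone deacetylase and demethylase lists did not pass, with adjusted p from 0.0822 to 0.271. Adjusted over the list alone, 1 acinar enzyme, oncofetal gene and erythroid marker more fell, and 1 mitosis gene and 1 immune marker fewer.

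Calls against adult acinar cells were shared between ADM cultures and each of the other groups. ADM and embryonic cells had 1345 genes higher in common, where independent calls would give 276, and 421 lower, where independent calls would give 24.5, with 32 genes called in opposite directions. ADM and tumor cells shared 1921 higher genes (388 for independent calls) and 740 lower genes (55.7), with 67 opposite. Of the 2766 genes called higher in ADM, 1345 were shared with embryonic and 1921 with tumor cells, and of the 935 called lower, 421 and 740. In 100 simulations of unchanged groups measured against the same simulated adult arrays, 0.01 to 0.02 genes were shared per direction on average. With no gene changed hardly any is called, so this small count was fixed in advance. It is no yardstick for the shared calls. Changes correlated across genes at r = 0.65 for ADM and embryonic and r = 0.76 for ADM and tumor cells, with covariances of 0.502 and 0.819. The simulations gave r = 0.50 and covariances of 0.0252 and 0.0253. That simulated r was also fixed in advance, because unchanged contrasts that share their control arrays correlate at 0.50 through noise alone. It is no yardstick for the r of real changes. Genes are not independent replicates, and with 3 adult arrays the controls could not be split into separate sets for each contrast. The same adult arrays therefore enter both contrasts.

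All 3 groups had 1045 genes higher than adult cells in common, and 375 lower. Among the 2766 genes higher in ADM, 292 were called higher still in tumor cells and 538 lower than in ADM. Among the 935 genes lower in ADM, 145 were called lower still in tumor cells and 26 higher. Over all genes, 727 were called higher and 1125 lower in tumor cells than in ADM. The ADM arrays that picked these genes also enter the comparison with tumor cells, which favours a return toward the adult level. The counts were not tested against what that choice alone would give.

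**Figure D4:**
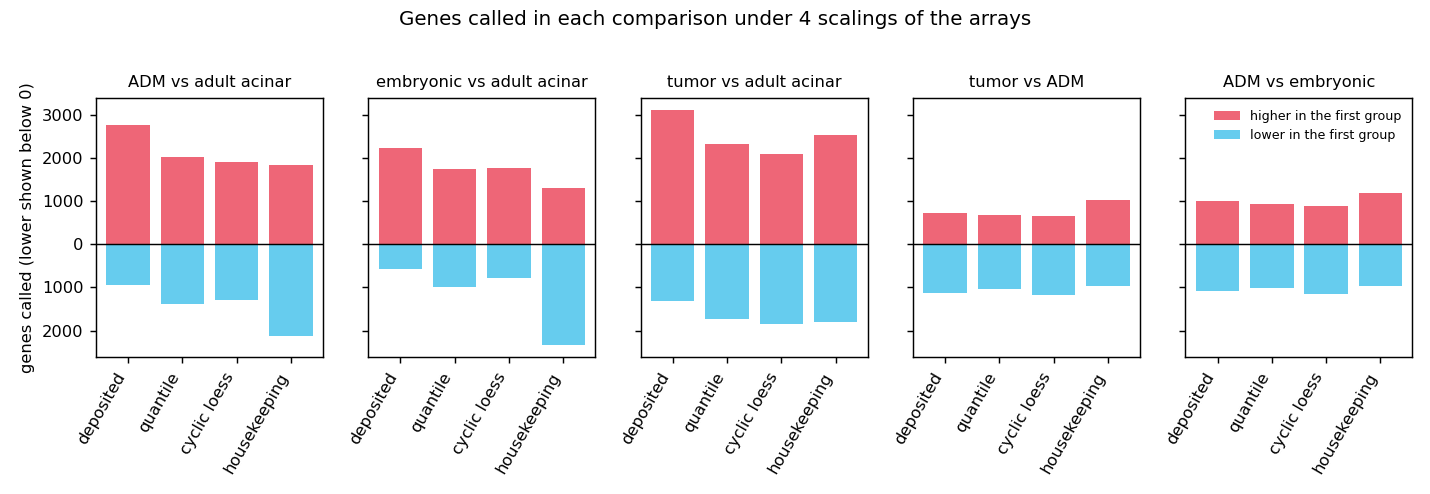
Number of genes called (vertical, lower calls drawn below 0) in each of 5 comparisons with the deposited values and after quantile normalization, cyclic loess and centring on housekeeping genes. For ADM against adult acinar cells, 2766 higher and 935 lower calls became 1840 higher and 2124 lower with housekeeping centring.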

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

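The tests of RNA from other cells and of chromosome gain or loss described here were chosen only after the results were seen. Signal in data outside the gene tests came from the 16010 probe sets with no gene symbol and the 1814 with several. Of the 16010, 628 were called higher in ADM cultures, 461 in embryonic and 648 in tumor cells, each against adult acinar cells. In the same order, 539, 414 and 566 were called lower. Calls in both directions made up 7.29%, 5.47% and 7.58% of the 16010. Of the 1814, 128, 134 and 191 were called higher and 75, 22 and 81 lower in the same order. In each of these comparisons the called share of the 1814 was larger than that of the 16010. No gene result uses either kind of probe set.

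Markers of 7 cell types other than acinar or ductal were higher on embryonic than on adult arrays. RNA from other cell types in the embryonic isolates stays open as a candidate explanation: 7 of 7 lists were called higher, but that count is the pattern itself and no separate test of it was run. With an estimated correlation the fibroblast list (adjusted p = 0.0599) and the erythroid list (adjusted p = 0.13) lost the call, and the erythroid list also lost it without some single arrays. All 7 lists were also called higher under both quantile normalization and cyclic loess, which argues only against scaling of the adult arrays that depends on signal level. Housekeeping centring moves all genes of an array alike. Such a shift barely alters a test of a list against all other genes, so it could not be tested this way. A real difference of embryonic acinar cells in these genes stays open and was not tested.

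Genes on chromosome 6 were higher, and those on chromosomes 1 and 4 lower, on tumor than on ADM arrays, with median shifts of 0.27, -0.31 and -0.23 on the log2 scale against all other genes. The chromosome 6 shift was at least 0.267 under both quantile normalization and cyclic loess, which argues only against normalization effects that depend on signal level. A shift of all genes of an array alike cancels in a value taken against all other genes. Among genes that differed by under 0.5 between the other 3 groups, the chromosome 6 shift was 0.35. That argues against clusters of genes that set those 3 groups apart. Genes particular to the tumor cells pass this filter, so clusters of them stay open. Gain or loss of whole chromosomes in the tumor cells may account for the shifts but stays undecided. The rule for it was set on chromosome 6 alone. The lowest chromosome 6 shift over the 3 tumor arrays and the 3 other groups was 0.2, exactly the bound it had to exceed. On chromosome 6, 9 of 10 windows of 30 genes lay above 0. On chromosome 1, 11 of 11 windows lay below 0, and on chromosome 4, 11 of 12. In a permutation by circular shifts of gene order, two-sided adjusted p was 0.064 for chromosome 1, 0.293 for chromosome 4 and 0.268 for chromosome 6.

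More genes were called higher than lower against adult cells, 74.7% of the ADM calls. Scaling of the adult arrays may account for part of this, since the share was 59.4% under cyclic loess and 59.4% under quantile normalization, narrowly under the 60% set for it and still with more higher than lower calls. The plan had also named housekeeping centring, under which the share was 46.4%, under the same bound and with more lower than higher calls. It shifts all genes of an array by the same amount. The share therefore depends on the scaling chosen, and whether that amount is right was not tested. The measurement floor on adult arrays cannot be told apart from a real rise: 49.9% of calls were higher among genes with an adult mean of at least 6, but that choice itself favours falls, and 72.2% were higher among genes whose mean over both groups was at least 6. A biological rise in more genes was not tested.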

How the results depend on the processing

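Every total of called genes (both directions) or lists kept within 1.5 times its value under the 3 normalizations, the dim gene filter, the 6-array fits, the intensity trend, array weights, probe set means and an adjusted p under 0.01, where it was counted. Lists were not counted again at that lower p, nor shared calls in the 6-array fits. The directions moved more: under housekeeping centring, ADM against adult went from 2766 higher and 935 lower to 1840 and 2124, and embryonic against adult from 2217 and 580 to 1306 and 2346, with 986 lower under quantile normalization. With no fold change minimum the calls numbered 7965, 6519, 8254, 3404 and 3897 for ADM, embryonic and tumor against adult, tumor against ADM and ADM against embryonic, and shared calls 4504 and 5618, as the rule then admits small changes. With an estimated correlation 5, 9, 5, 4 and 14 lists were called in the same order. Leaving out each array in turn gave 3576 to 3855, 2554 to 2942, 4351 to 4624, 1620 to 2346 and 1976 to 2103 called genes, with 20 to 21, 21 to 23, 18 to 19, 15 to 17 and 22 to 25 lists. Shared calls then numbered 1609 to 1885 with embryonic and 2576 to 2793 with tumor cells. The highest count for tumor against ADM, 2346, came without tumor replicate 1. That array had the lowest array weight of all, 0.438, against 0.969 and 1.32 for the other tumor arrays. Of 535 called values of named genes, 56 lost their call under some alternative, 36 of them under a normalization and 37 with 1 array left out. Of 103 called lists 67 lost it, 17 of them under an alternative other than the estimated correlation. No called gene changed direction, and 1 called list median changed sign, PRC1 in ADM against adult, which was -0.0017 under housekeeping centring. The causes were not tested. Signal over background limits values near 3.62: the dimmer group of 433, 429, 634, 451 and 455 called genes lay there.

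With the replicate number as a block, 3702, 2799, 4431, 1834 and 2093 genes were called, against 3701, 2797, 4429, 1852 and 2098 without it. Across groups, the deviations of arrays with the same number correlated across genes by 0.0013 on average over 18 pairs (-0.0476 to 0.128), and 5 of 12 arrays correlated best with an array of their own number.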

Other observations

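The levels in this part were chosen after the data were seen, and the counts of splits were planned. Sex-linked genes differed between the groups. Xist, the transcript that coats the inactive X chromosome, stood at 10.31 ± 0.049 (SD, n = 3) on adult, 9.02 ± 0.325 on embryonic and 9.92 ± 0.087 on ADM arrays, and at 3.85 ± 0.699 on tumor arrays. The Y-linked gene Eif2s3y stood at 3.93 on adult, 6.14 on embryonic, 3.47 on ADM and 7.00 on tumor arrays, and Uty, also Y-linked, at 2.96, 4.19, 2.56 and 5.06. On embryonic arrays both Xist and Uty lay above the background level of 3.62. Adult and ADM arrays were alike, with Xist far above that level and Uty under it. Tumor arrays had Uty above it and Xist close to it. The sex of the animals is not given in the labels. Because these genes differ with the group, sex cannot be separated from the group in any comparison with tumor or embryonic cells.

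Around the Cdkn2a locus, Mtap, a gene of methionine salvage next to it, stood at 6.25 ± 0.354 (SD, n = 3) on adult, 6.49 ± 0.162 on embryonic and 7.74 ± 0.186 on ADM arrays, and at 3.25 ± 0.364, under the background level, on tumor arrays. Cdkn2a itself lay at 3.85 on adult, 3.46 on embryonic, 4.56 on ADM and 3.60 on tumor arrays, and Cdkn2b at 4.82, 4.58, 6.76 and 4.27. The tumor level of Cdkn2a was not called different from the adult level (adjusted p = 0.272). The more distant neighbours Klhl9 and Plaa stood at 7.88 and 7.90 on tumor and 8.08 and 8.20 on ADM arrays. No test of a deletion was run.

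For each of the 5 comparisons, 1 of the 10 splits of its 6 arrays, the real one, gave as many calls. The real splits gave 3701, 2797, 4429, 1852 and 2098 called genes and the highest of the other splits 0 in each case, and 10 splits are too few for a share under 0.05.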
